A study of Mus musculus with 6 samples.

How the data were processed

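Total RNA from 6 cultures of C3H10T1/2 adipocytes was hybridised, biotin labelled, to 1 Affymetrix Mouse Gene ST array each, per the labels. The labels name 3 biological replicates with scramble shRNA and 3 with Zc3h10 shRNA, and these replicate titles gave the groups. The deposited values are summarised probe set intensities on a linear scale, 1 value per probe set and array, with no pooling of replicates. The scale was read from the values: none lay below 0, array maxima were 12519 to 13202, and the quartiles of the 6 arrays were nearly equal, so the arrays had been scaled to each other before deposit and were not centred. Affymetrix Expression Console and Partek 6.6 are named in the submitters' processing notes, without a role or order. The background correction, summarisation and normalization methods are not given in the sources used here, which matters most for dim probe sets, whose log2 changes depend on the background removed. Scanner files were not used here, so the background correction itself could not be varied.

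Log2 was taken of the intensities with no pseudocount and no further scaling. Each of 33079 probe sets was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 4 residual and 4.00 prior degrees of freedom, two-sided). Benjamini-Hochberg adjustment covered all probe sets, because the table marks no control probes, and carries no detection calls. The threshold was an adjusted p under 0.05, the 5% of the series' design text. The effect is the mean log2 of Zc3h10 shRNA minus the mean log2 of scramble. The groups of 3 arrays did not overlap for 9110 probe sets (27.5%), where chance gives 10%. No pair of arrays held the same values. The level of Zc3h10 was also compared with a two-sided exact permutation test.

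Genes were named from the platform annotation, with symbols checked by gene number against the RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 23043 had 1 gene symbol, 1740 had several and 8296 were unnamed here, and no name was taken from a probe set with several. The check changed 0 symbols, and 169 gene numbers were without a match in that table. Of the changed probe sets, 507 had no single symbol. The RefSeq table served only for names, gene types and the order of neighbouring genes, since the build behind the array values is not given in the sources used here. Where a gene had several probe sets, the one with the highest mean over the 6 arrays stood for it, which left 21996 genes. Probe sets of paralogs, pseudogenes and overlapping genes can bind each other's transcripts.

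The design, the tests, the naming rule, the gene lists and the alternatives were fixed before the data were examined. The rule named Zc3h10, then the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05 and no overlap between groups. It left out predicted or unnamed genes, microRNA and small RNA genes, and olfactory and vomeronasal receptors. It added a fixed set of adipocyte genes whatever their value, and up to 4 genes per list with the smallest p. Of the genes under the rule, 158 passed the threshold, and 126 of them passed without each single array in turn. Actb, also in the fixed set, was not analysed here. A few members named outside the rule, such as Mcm6, Pdgfra, Fzd4, Wars and several mitochondrial synthetases, were chosen after their values were seen.

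Of 39 gene lists, 38 had at least 5 measured members and were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the 38 lists. The list of 13 mitochondrially encoded messenger RNAs was not analysed here. Camera called 23 lists, 16 lower and 7 higher. With the correlation estimated from 4 residual degrees of freedom, 0 of the 38 were called, with adjusted p values of 0.138 to 0.427 among those 23 lists and 11 lists at an unadjusted p under 0.05. The fry test, which asks whether a list's genes move 1 way on balance, called 27. Lists shared 25 genes, so their results are not independent.

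The code was tested on simulated data with 200 changed probe sets among 33079 for this comparison. Noise was drawn independently for each probe set. The changed ones were taken from those at or above the median level, so the recovery does not cover dim probe sets. limma recovered 41.8% of those changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 3-fold, and called 10 of 32879 without a change, while an ordinary t statistic recovered 0%, 8.96% and 19.7%. The simulated share of changed probe sets was smaller than the 9.79% called in the data. This makes the adjustment stricter in the simulation, so the recovery of either test need not carry over. Among 38 simulated lists over 21996 genes, camera called the 1 list shifted by −0.4 (adjusted p = 0.0323 with an estimated correlation) and 0 of the others. Alternatives were other scalings (quantile, median, cyclic loess), an offset of 32 before log2, filters on dim probe sets, an ordinary t statistic, an intensity trend or array weights in limma, the replicate number as a block, other thresholds, other ways to combine probe sets, and each array left out. Figures were drawn with matplotlib 3.10.9.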

Results

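Gene expression was measured on single-colour Affymetrix Mouse Gene ST arrays in adipocytes made from C3H10T1/2 cells, a mouse mesenchymal line that can be turned into fat cells in culture. All cultures are given as 9 days of differentiation and a 72 h exposure to adenovirus at a multiplicity of infection of 50. How the exposure fell within the 9 days is not given in the sources used here. In 3 biological replicates the virus carried a scrambled short hairpin RNA (scramble), and in 3 it carried a hairpin against Zc3h10 (Zc3h10 shRNA), the gene of a CCCH zinc finger RNA-binding protein. The comparison asks which transcripts differ in these adipocytes when the hairpin targets Zc3h10. Median intensities over 33079 probe sets were 15.6, 15.6 and 15.7 on scramble arrays 1 to 3 and 15.7, 16.1 and 15.7 on shRNA arrays 1 to 3. Log2 values correlated across probe sets at r of 0.992 to 0.994 within a group (6 pairs) and 0.985 to 0.988 between groups (9 pairs). The first principal component, with 50.6% of the variance, separated the groups. The number of arrays, 3 per group, limits the precision of every value, and log2 changes are Zc3h10 shRNA minus scramble with the standard error (SE) of the limma fit.

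In adipocytes given the Zc3h10 hairpin, most measured markers of mature fat cells fell, as did most genes of lipid synthesis, lipid storage, fatty acid oxidation and cholesterol synthesis. Some subunits of the respiratory chain and some markers of brown and beige fat cells fell too. Many cell cycle genes rose, and so did some genes of the actin cytoskeleton and the contractile apparatus. Zc3h10 itself did not pass the threshold.

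The Zc3h10 transcript, read by probe set 17246198, averaged 33.4 ± 6.77 intensity units (SD, n = 3) on the scramble arrays and 26.1 ± 3.72 (SD, n = 3) on the Zc3h10 shRNA arrays. The values were 25.9, 39.0 and 35.3 for scramble replicates 1 to 3 and 25.2, 30.2 and 22.9 for shRNA replicates 1 to 3. The log2 difference was −0.34 ± 0.17, or 1.27-fold lower, which corresponds to 78.8% of the scramble level with a 95% confidence interval of 60.0 to 103%. This did not pass the threshold (limma, adjusted p = 0.301), and a two-sided exact permutation test gave p = 0.2, where 0.1 is the smallest that 3 against 3 arrays allow. The difference went in the direction the labels name, with all 3 shRNA arrays below the scramble mean, but scramble replicate 1 lay inside the range of the shRNA arrays. Without scramble replicate 1 it was −0.52 (adjusted p = 0.0810), and without scramble replicate 2 it was −0.22 (adjusted p = 0.588).

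Across the array, 3238 of 33079 probe sets (9.79%) changed at an adjusted p under 0.05, 1426 higher and 1812 lower in the Zc3h10 shRNA cells. Changes of at least 2-fold were found for 138 probe sets that rose and 344 that fell. Among 21996 named genes, 2663 changed. The largest rise among genes covered by the naming rule was that of Colec10, a collagen-containing C-type lectin, at 2.99 ± 0.15 (7.95-fold, adjusted p = 0.000549). It was followed by Sprr1a, a small proline-rich protein of the cornified envelope, at 2.70 ± 0.12, and Cemip, which takes part in hyaluronan breakdown, at 2.54 ± 0.25. The chemokine gene Ccl2 rose by 2.40 ± 0.16 (adjusted p = 0.000658) and Vip, the gene of vasoactive intestinal peptide, by 2.30 ± 0.13. Rises were also measured for Sprr2k (2.26), Tmem176b (1.90), the imprinted noncoding RNA Rian (1.81), Ms4a4d (1.78), the lysophospholipid acyltransferase Mboat1 (1.71), fibroblast activation protein, Fap (1.63), and the neutral sphingomyelinase Smpd3 (1.63). Scramble mean log2 values of Cemip (3.81), Vip (4.23), Sprr2k (3.07) and Fap (3.55) lay under 4.34, the upper limit of the central 95% of olfactory and vomeronasal receptor genes, mostly silent outside sensory tissue. The size and order of these rises are therefore uncertain.

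The largest falls under the same rule were in genes that include several of lipid and glycogen metabolism. Olr1, a receptor for oxidised lipoprotein, was at −2.77 ± 0.38 (6.84-fold lower, adjusted p = 0.00365), and Gys2, a glycogen synthase, at −2.76 ± 0.22 (6.75-fold lower, adjusted p = 0.000678). Klb, the β-Klotho co-receptor of fibroblast growth factor hormones, was at −2.52 ± 0.22, and the lipid droplet protein gene Cidea at −2.39 ± 0.21. Abcd2, a peroxisomal transporter of very long fatty acyl groups, was at −2.27 ± 0.23, the amino acid transporter Slc36a2 at −2.16 ± 0.11, and the fatty acid elongase Elovl3 at −2.11 ± 0.14. The other genes were Tmem45b (−2.44), the class I histocompatibility gene H2-K1 (−2.41), B3galt2 (−2.05), Cyp2b10 (−2.04) and the carbonic anhydrase Car2 (−2.04). H2-K1, Cyp2b10 and Sprr2k have close paralogs whose transcripts can bind the same probes, so their values are uncertain. Olr1 and Klb had shRNA mean log2 values of 4.13 and 3.90, also under 4.34, so the size and order of these falls are uncertain too. With an ordinary t statistic in place of the moderated one, Olr1 (adjusted p = 0.0739) and Cyp2b10 (adjusted p = 0.0669) missed the threshold. With 1 array left out, the number of changed probe sets was 1807 without scramble replicate 2, 2030 without scramble replicate 3, 2068 without shRNA replicate 2 and 1959 without shRNA replicate 3.

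**Figure D1:**
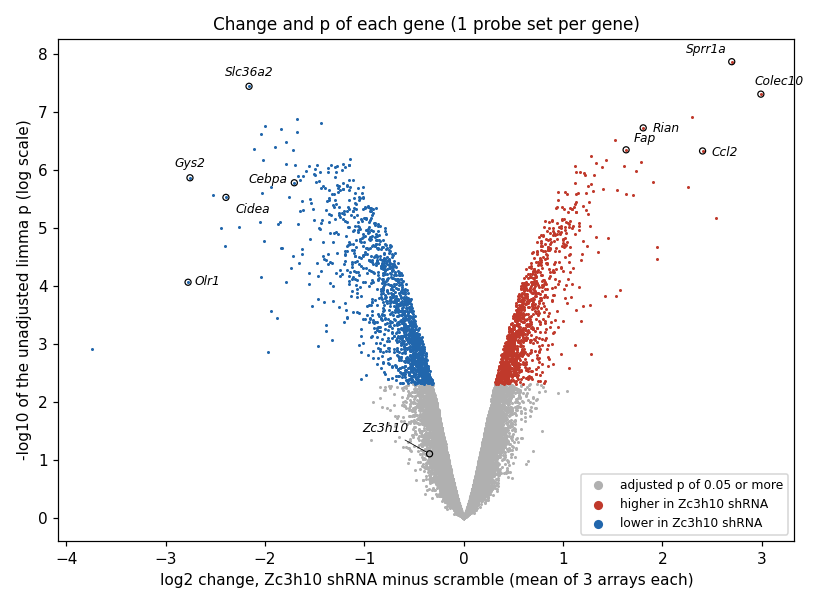
Each point is a gene, with its log2 change (Zc3h10 shRNA minus scramble, 3 arrays per group) on the horizontal axis and −log10 of its unadjusted limma p on the vertical axis; red and blue points passed an adjusted p of 0.05. Colec10 at 2.99 lies farthest right, Olr1 at −2.77 is among the farthest left, and Zc3h10 at −0.34 lies among the grey points.

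Genes of the mature adipocyte fell almost as a whole. Of 25 measured markers, 23 fell, also 23 when adjusted over the list alone, with a median log2 change of −1.07 (camera, adjusted p = 3.03e-25; adjusted p = 0.138 with an estimated correlation). The adiponectin gene Adipoq was at −0.84 ± 0.08, the lipid droplet coat gene Plin1 at −1.16 ± 0.09, lipoprotein lipase, Lpl, at −1.17 ± 0.11, and the fatty acid carrier gene Fabp4 at −0.66 ± 0.09. The insulin-responsive glucose transporter gene Slc2a4 was at −1.53 ± 0.14 (2.89-fold lower, adjusted p = 0.000846) and the glycerol channel gene Aqp7 at −1.70 ± 0.13. Among 19 adipogenic transcription factors, 10 fell, with 12 lower and 1 higher adjusted over the list alone and a median of −0.36 (camera, adjusted p = 4.48e-06; adjusted p = 0.138 with an estimated correlation). These included the adipogenic regulators Pparg (−0.96 ± 0.12) and Cebpa (−1.71 ± 0.14), and the lipogenic regulators Srebf1 (−0.90 ± 0.09) and Mlxipl (−1.41 ± 0.17). Cebpb, which acts early in adipogenesis, was at −0.41 ± 0.12 and did not pass (adjusted p = 0.0739), although it passed with probe sets under the median level left out (adjusted p = 0.0308) and with an intensity trend in the limma prior (0.0214). The count for the transcription factors was 5 or 6 without any one of scramble replicates 2 and 3 and shRNA replicates 1 to 3, and 6 with the ordinary t statistic.

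Of 19 markers of brown and beige adipocytes, 9 fell, 11 adjusted over the list alone, with a median of −0.46 (camera, adjusted p = 4.48e-06; adjusted p = 0.138 with an estimated correlation). Besides Cidea and Elovl3, these were led by Cox8b, a cytochrome c oxidase subunit, at −1.72 ± 0.12 and the proton channel gene Otop1 at −1.08 ± 0.14. The thermogenic uncoupling protein gene Ucp1 had a low signal, with a scramble mean log2 of 4.00, and a change of −0.46 ± 0.13 that did not pass (adjusted p = 0.0628). Without scramble replicate 3 the change of Ucp1 was −0.59 (adjusted p = 0.0217), and it passed with probe sets under the lower quartile of level left out (0.0469). The coactivator gene Ppargc1a was at −0.14 ± 0.15 (adjusted p = 0.667), so no difference was detectable.

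**Figure D2:**
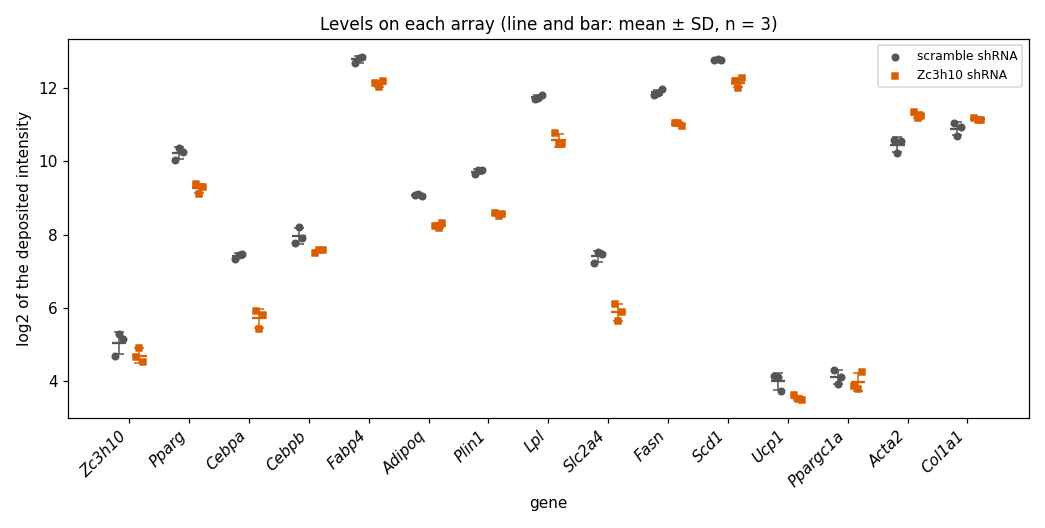
Log2 intensity of Zc3h10 and of 14 genes fixed in advance on each of the 6 arrays, with horizontal lines for group means and bars for the SD (n = 3). The groups lie apart for Pparg, Cebpa, Fabp4, Adipoq, Plin1, Lpl, Slc2a4, Fasn and Scd1, all lower with Zc3h10 shRNA, and overlap for Zc3h10.

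Lipid synthesis and lipid storage genes fell as well. In fatty acid and triglyceride synthesis, 14 of 24 genes fell, with 18 lower and 1 higher adjusted over the list alone and a median of −0.61 (camera, adjusted p = 2.68e-13; adjusted p = 0.138 with an estimated correlation). Dgat2, which makes triglyceride from diacylglycerol, was at −1.67 ± 0.13 (3.19-fold lower), ATP citrate lyase, Acly, at −1.28 ± 0.10, fatty acid synthase, Fasn, at −0.87 ± 0.09, and the desaturase gene Scd1 at −0.62 ± 0.10. Among lipolysis and lipid droplet proteins, 14 of 18 fell, 15 adjusted over the list alone, with a median of −1.05 (camera, adjusted p = 4.16e-15; adjusted p = 0.138 with an estimated correlation). Pde3b, the phosphodiesterase through which insulin restrains lipolysis, was at −1.48 ± 0.11 and Plin4 at −1.34 ± 0.10. In cholesterol synthesis, 16 of 19 fell, 18 adjusted over the list alone, with a median of −0.78 (camera, adjusted p = 3.48e-16; adjusted p = 0.154 with an estimated correlation). Dhcr7, the enzyme of the last step, was at −1.27 ± 0.11, Nsdhl at −1.22 ± 0.10 and Fdps, which makes farnesyl diphosphate, at −1.21 ± 0.12. In glycolysis and glucose uptake, 12 of 21 fell, with 14 lower and 1 higher adjusted over the list alone and a median of −0.63 (camera, adjusted p = 3.29e-08; adjusted p = 0.154 with an estimated correlation). Hexokinase Hk2 was at −1.37 ± 0.10, the monocarboxylate transporter gene Slc16a1 at −1.28 ± 0.10, and Pdk1, a kinase that restrains pyruvate dehydrogenase, at −1.55 ± 0.17.

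Mitochondrial oxidation genes were lower too. In fatty acid oxidation, 20 of 22 genes fell, 21 adjusted over the list alone, with a median of −0.82 (camera, adjusted p = 1.89e-20; adjusted p = 0.138 with an estimated correlation). Ehhadh, an enzyme of peroxisomal β-oxidation, was at −2.02 ± 0.14 (4.05-fold lower), Echs1 at −1.35 ± 0.11 and the carnitine palmitoyltransferase gene Cpt2 at −1.25 ± 0.11. In the tricarboxylic acid cycle, 18 of 21 fell, 20 adjusted over the list alone, with a median of −0.57 (camera, adjusted p = 6.08e-16; adjusted p = 0.154 with an estimated correlation). The pyruvate dehydrogenase component Dlat was at −1.26 ± 0.10, isocitrate dehydrogenase Idh3a at −1.31 ± 0.14 and citrate synthase, Cs, at −0.71 ± 0.09. This count was 11 without scramble replicate 2 and 11 without scramble replicate 3.

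Some subunits of the respiratory chain were lower. For complex II to IV, 12 of 23 fell, 19 adjusted over the list alone, with a median of −0.39 (camera, adjusted p = 1.11e-11; adjusted p = 0.154 with an estimated correlation), including cytochrome c, Cycs, at −1.11 ± 0.11 and Uqcrc1 at −0.72 ± 0.10. For complex I, 11 of 31 fell, 16 adjusted over the list alone, with a median of −0.29 (camera, adjusted p = 7.18e-10; adjusted p = 0.192 with an estimated correlation), among them Ndufb8 (−0.93 ± 0.11) and Ndufs1 (−0.73 ± 0.11). For ATP synthase, 4 of 15 fell, with 10 lower and 1 higher adjusted over the list alone and a median of −0.30 (camera, adjusted p = 0.000207; adjusted p = 0.190 with an estimated correlation). The catalytic-core gene Atp5a1 was at −0.65 ± 0.08. Of 55 mitochondrial ribosomal proteins, 10 fell, 24 adjusted over the list alone, with a median of −0.27 (camera, adjusted p = 3.10e-11; adjusted p = 0.192 with an estimated correlation), among them Mrpl12 (−0.88 ± 0.10) and Mrpl10 (−0.86 ± 0.10). Of 32 genes of mitochondrial biogenesis, import and dynamics, 13 fell, 16 adjusted over the list alone, with a median of −0.35 (camera, adjusted p = 3.71e-09; adjusted p = 0.187 with an estimated correlation). The chaperonin gene Hspd1 was at −0.78 ± 0.12, the inner-membrane fusion gene Opa1 at −0.71 ± 0.11 and the peroxiredoxin gene Prdx3 at −0.69 ± 0.09. Counts shrank with 1 array left out: to 7 for complex I without shRNA replicate 3, to 6 for ribosomal proteins without scramble replicate 2, shRNA replicate 1 or shRNA replicate 3, and, without any one of scramble replicates 2 and 3 and shRNA replicates 2 and 3, to 1 or 2 for ATP synthase and 7 or 8 for biogenesis. By the ordinary t statistic, 6 genes of complex I and 7 of complex II to IV passed.

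**Figure D3:**
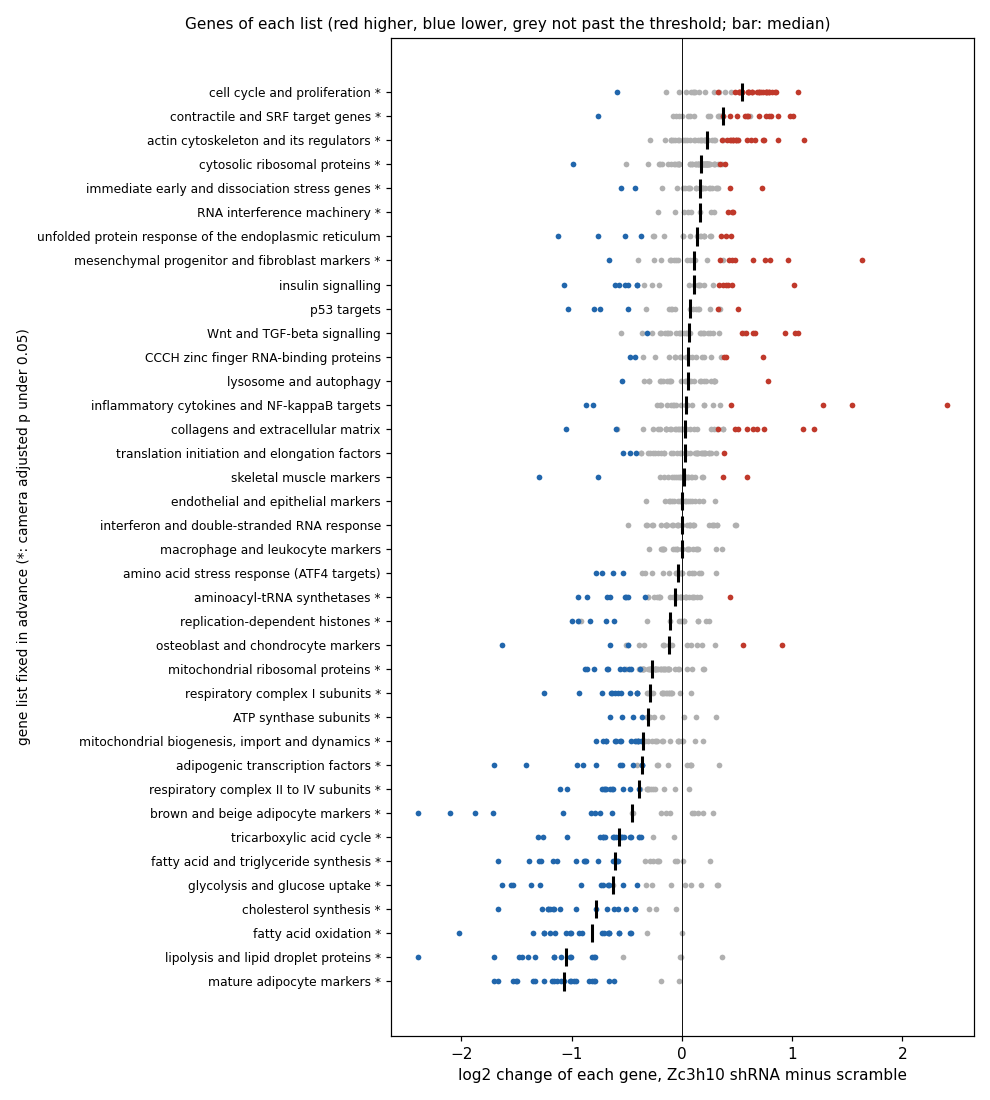
Points are the log2 changes (Zc3h10 shRNA minus scramble, horizontal axis) of the genes in each of 38 lists (vertical axis), coloured where the gene passed an adjusted p of 0.05, and vertical bars are list medians. Mature adipocyte markers have the lowest median, −1.07, and cell cycle genes the highest, 0.54.

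Many cell cycle genes were higher in the Zc3h10 shRNA cells. Of 40 measured, 26 rose and Mcm6 fell, with 29 higher and 1 lower adjusted over the list alone and a median of 0.54 (camera, adjusted p = 2.89e-13; adjusted p = 0.161 with an estimated correlation). The proliferation marker Mki67 was at 1.05 ± 0.14 (2.07-fold higher, adjusted p = 0.00340), topoisomerase Top2a at 0.79 ± 0.11, the kinetochore motor gene Cenpe at 0.79 ± 0.11 and cyclin gene Ccnd1 at 0.70 ± 0.10. The 26 rises became 13 without scramble replicate 2 and 15 without scramble replicate 3, shRNA replicate 1 or shRNA replicate 3. Mcm6 was lost without any one array except shRNA replicate 1. The ordinary t statistic called 8 of the 40 genes, Mki67 not among them (adjusted p = 0.0515). Some replication-dependent histones went the other way: 5 of 17 fell, 6 adjusted over the list alone, with a median of −0.11 (camera, adjusted p = 0.00813; adjusted p = 0.427 with an estimated correlation). Linker histone genes H1f3 (−0.95 ± 0.11) and H1f2 (−0.84 ± 0.11) and the core histone gene H4c1 (adjusted p = 0.00889, or 0.0913 with the ordinary t statistic, which called 2 of the list) were among them. Near-identical histone copies can share probes, and the shRNA levels of H1f3 (3.70) and H4c1 (3.64) lay within background. The 5 histones became 3 without any one of scramble replicates 1 to 3 and shRNA replicate 2, and the list was not called without shRNA replicate 2 (adjusted p = 0.0534).

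Some cytoskeletal and contractile genes rose. Of 29 contractile and serum response factor target genes, 13 rose and Des fell, with 20 higher and 1 lower adjusted over the list alone and a median of 0.37 (camera, adjusted p = 7.67e-09; adjusted p = 0.154 with an estimated correlation). The smooth muscle genes Tagln, Myl9 and Acta2 were at 1.01 ± 0.11, 0.98 ± 0.10 and 0.80 ± 0.12, and the matricellular gene Ccn1 at 0.76 ± 0.09. Of 45 genes of the actin cytoskeleton and its regulators, 16 rose, with 20 higher and 1 lower adjusted over the list alone and a median of 0.23 (camera, adjusted p = 3.94e-08; adjusted p = 0.154 with an estimated correlation). The focal adhesion genes Zyx and Tln1 were at 1.11 ± 0.10 and 0.73 ± 0.10, and the actin cross-linker gene Flna at 0.87 ± 0.10. Without scramble replicate 3 the contractile count was 8, and without any one of scramble replicates 2 and 3 and shRNA replicates 1 to 3 the actin count was 7 to 10. Des was lost without any 1 array (largest adjusted p = 0.138, without shRNA replicate 2), and its shRNA level (4.18) lay within background. The ordinary t statistic called 7 of the contractile genes, Acta2 not among them (adjusted p = 0.0515).

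Of 24 markers of mesenchymal progenitors and fibroblasts, 9 rose and Pdgfra fell, with 9 higher and 2 lower adjusted over the list alone and a median of 0.11 (camera, adjusted p = 0.00758; adjusted p = 0.258 with an estimated correlation). Fap rose from a scramble level within background, with Eng, a co-receptor of transforming growth factor β, at 0.96 ± 0.12, the homeobox gene Prrx1 at 0.80 ± 0.09 and the hyaluronan receptor gene Cd44 at 0.64 ± 0.09. Without scramble replicate 2 the 9 rises became 5. The list of collagens and extracellular matrix was not called (39 genes, median 0.03, camera, adjusted p = 0.150), although 9 members rose and 2 fell, 13 and 4 adjusted over the list alone. Fibronectin, Fn1, was at 1.20 ± 0.11, Col12a1 at 1.09 ± 0.10, Col15a1 at −1.05 ± 0.15 and Col1a1 at 0.26 ± 0.11 (adjusted p = 0.204, or 0.0483 with an intensity trend in the prior). This list was called without scramble replicate 1 (adjusted p = 0.0475). The ordinary t statistic called 6 of its genes, Col15a1 not among them (adjusted p = 0.0579). In Wnt and transforming growth factor β signalling, 7 of 34 rose and Fzd4 fell, 10 and 3 adjusted over the list alone, with a median of 0.06 (camera, adjusted p = 0.0602). Its risers included the ligand genes Tgfb2 (1.05 ± 0.10) and Bmp4 (1.02 ± 0.11) and the inhibitory helix-loop-helix gene Id2 (0.93 ± 0.12). This list was called by the fry test (adjusted p = 0.00623), after quantile normalization (0.0375) and without scramble replicate 1 (0.0475), scramble replicate 3 (0.0370) or shRNA replicate 3 (0.0489). Fzd4 was lost without any one array except shRNA replicate 1.

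Lists of cytosolic translation had small medians, and some mitochondrial synthetases fell. Of 54 cytosolic ribosomal proteins, Rps4x (0.39 ± 0.08) and Rps19 (0.35 ± 0.08) rose and Rpl23a (−0.99 ± 0.11) fell, with 1 higher and 1 lower adjusted over the list alone and a median of 0.17 (camera, adjusted p = 0.00197; adjusted p = 0.202 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes that can share probes. Of 34 aminoacyl-tRNA synthetases, 8 fell and Wars rose, also 8 and 1 adjusted over the list alone, with a median of −0.07 (camera, adjusted p = 0.00331; adjusted p = 0.154 with an estimated correlation). The synthetases that fell, Lars2 (−0.94 ± 0.10), Mars2, Iars2 (−0.67 ± 0.10), Yars2 (−0.65 ± 0.09), Nars2, Fars2, Hars2 and Rars2, are mitochondrial forms. Mitochondrial forms were not a list of their own and were not tested as a group. The list of translation initiation and elongation factors was not called (38 genes, 1 higher and 3 lower, 2 and 3 adjusted over the list alone, median 0.03, mean −0.02, test direction lower, camera, adjusted p = 0.950). Eif4a1 was at −0.53 ± 0.10. The falls of this list numbered 1, 1 and 0 without scramble replicate 2, scramble replicate 3 and shRNA replicate 3, and the rise was lost without any one array except shRNA replicate 1. Of the ribosomal proteins 8, and of these factors 10, passed by the ordinary t statistic. Rps19 lost its call without any 1 array (largest adjusted p = 0.126, without scramble replicate 3) and Rps4x without any except shRNA replicate 1 (largest adjusted p = 0.0793, without scramble replicate 2). Mars2 lost it without scramble replicate 2 (adjusted p = 0.0508) and with the ordinary t statistic (0.0943, 5 synthetases called), and Wars without any one of scramble replicates 2 and 3 and shRNA replicates 2 and 3. Eif4a1 lost it without scramble replicate 3 (adjusted p = 0.0526) or shRNA replicate 3 (0.0535), and the synthetase falls numbered 4 or 5 without scramble replicate 1, scramble replicate 2, shRNA replicate 2 or shRNA replicate 3.

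Of 11 RNA interference genes, Dicer1 (0.46 ± 0.09), Ago1 (0.45 ± 0.09) and Tnrc6c (0.42 ± 0.09) rose, 5 adjusted over the list alone, with a median of 0.16 (camera, adjusted p = 0.0183; adjusted p = 0.154 with an estimated correlation). These rises numbered 1 without scramble replicate 2 or 3 and 0 without shRNA replicate 2 or 3 (limma, where 5 passed at an unadjusted p under 0.05 with all arrays and 5 by the ordinary t statistic), and the list was not called without shRNA replicate 1 (adjusted p = 0.0552). Of 25 immediate early and dissociation stress genes, Dusp1 (0.73 ± 0.11) and Atf3 (0.44 ± 0.10) rose and Nr4a1 (−0.55 ± 0.10) and Zfp36 (−0.43 ± 0.10) fell, 2 and 2 also adjusted over the list alone, with a median of 0.17 (camera, adjusted p = 0.0271; adjusted p = 0.154 with an estimated correlation). That list was not called without shRNA replicate 2 (adjusted p = 0.0504), with the mean of a gene's probe sets (0.0595) or with dim probe sets left out (0.0579). The ordinary t statistic called 2 of its genes, and only Dusp1 kept its call without each single array. Of 21 CCCH zinc finger genes, 3 rose and 2 fell, 4 and 3 adjusted over the list alone (median 0.06, camera, adjusted p = 0.489), led by the ribonuclease gene Zc3h12b at 0.73 ± 0.12. Of these 5 genes only Zc3h12b kept its call without each single array. It missed the threshold with the ordinary t statistic (adjusted p = 0.0614, 1 gene called), and the fry test called the list (adjusted p = 0.0250).

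The lists of ATF4 targets, the unfolded protein response, insulin signalling, p53 targets, lysosome and inflammatory genes were not called by camera, and most held genes of both directions. The fry test called ATF4 targets (adjusted p = 0.00835), inflammatory genes (0.0194) and lysosome genes (0.0499). Among 22 targets of ATF4, 4 fell, 6 adjusted over the list alone (median −0.04, camera, adjusted p = 0.0632), including Vldlr (−0.78 ± 0.10) and Nupr1 (−0.73 ± 0.10). This list was called without scramble replicate 2 (adjusted p = 0.0447), scramble replicate 3 (0.0423) or shRNA replicate 1 (0.0496). In the unfolded protein response, 3 of 21 rose and 4 fell, 5 and 6 adjusted over the list alone (median 0.13, mean −0.03, test direction higher, camera, adjusted p = 0.858), with Dnajb9 at −1.12 ± 0.14 and the transcription factor gene Xbp1 at −0.76 ± 0.10. In insulin signalling, 6 of 23 rose and 7 fell, 7 and 8 adjusted over the list alone (median 0.11, mean −0.03, test direction lower, camera, adjusted p = 0.858). Igf1r, the receptor of insulin-like growth factor, was at 1.01 ± 0.11 and its ligand gene Igf1 at −1.07 ± 0.18 (adjusted p = 0.0862 with the ordinary t statistic). Among 19 p53 targets, 2 rose and 4 fell, 5 and 5 adjusted over the list alone (median 0.07, mean −0.07, test direction lower, camera, adjusted p = 0.950), with the cell cycle inhibitor gene Cdkn1a at −0.79 ± 0.08. For lysosome and autophagy, Npc1 (0.78 ± 0.10) rose and Atg7 (−0.54 ± 0.12) fell among 28, 1 and 2 adjusted over the list alone (median 0.05, camera, adjusted p = 0.816). Among 24 inflammatory cytokines and NF-κB targets, 4 rose and 2 fell, 5 and 2 adjusted over the list alone (median 0.04, camera, adjusted p = 0.334), with prostaglandin synthase Ptgs2 at 1.55 ± 0.13 and Csf1 at 1.28 ± 0.10 after Ccl2. Atg7 lost its call without any one array except scramble replicate 3 (largest adjusted p = 0.101, without shRNA replicate 3), and insulin signalling rises numbered 1 without any one array except shRNA replicate 1, with falls of 2, 4 and 3 without scramble replicate 2, scramble replicate 3 and shRNA replicate 2. Other counts also shrank: ATF4 falls to 2 without scramble replicate 2, scramble replicate 3 or shRNA replicate 3, p53 falls to 2 without scramble replicate 1, scramble replicate 2, shRNA replicate 2 or shRNA replicate 3, and the unfolded protein and p53 rises to 1 or fewer without any 1 array. The inflammatory falls became 1 or fewer without scramble replicate 2, scramble replicate 3, shRNA replicate 1 or shRNA replicate 3. With the ordinary t statistic, 7 insulin signalling, 3 p53 and 3 inflammatory genes passed.

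Markers of other cell types differed by list. For macrophages and leukocytes, 0 of 21 genes passed, 0 adjusted over the list alone (limma, 3 at an unadjusted p under 0.05 and 1 by the ordinary t statistic, median −0.00, camera, adjusted p = 0.832). For endothelium and epithelium, 0 of 19 passed by limma, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by the ordinary t statistic (median 0.00, mean 0.01, test direction lower, camera, adjusted p = 0.950). For the interferon and double-stranded RNA response, 0 of 31 passed by limma, 0 adjusted over the list alone, 5 at an unadjusted p under 0.05 and 0 by the ordinary t statistic (median −0.00, mean 0.02, test direction higher, camera, adjusted p = 0.950). The interferon list was called higher without scramble replicate 3 (median 0.10, adjusted p = 0.0489), where 2 genes passed, and 1 passed without shRNA replicate 1. Of 25 skeletal muscle markers, Actn3 and Myh8 rose and Des and myoglobin, Mb (−1.30 ± 0.13), fell, 2 and 2 also adjusted over the list alone (median 0.02, mean −0.04, test direction lower, camera, adjusted p = 0.891). Actn3 lost its call without scramble replicate 3 (adjusted p = 0.0547) and with the ordinary t statistic (0.0685), and Myh8 without any 1 array (largest adjusted p = 0.130, without scramble replicate 1). Of 19 osteoblast and chondrocyte markers, 2 rose and 3 fell, 2 and 6 adjusted over the list alone (median −0.12, camera, adjusted p = 0.174), with bone sialoprotein, Ibsp, at −1.63 ± 0.19 and Dmp1 at 0.91 ± 0.12, and the falls numbered 1 without scramble replicate 3. In the ordinary t statistic, 1 muscle and 3 osteoblast and chondrocyte markers passed. The scramble level of Dmp1 (4.02) and both levels of Myh8 (2.55 and 2.93) lay within background.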

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

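All alternatives were planned. No named gene reversed under those run for genes. No list reversed under those run for lists, which left out cyclic loess, the lower-quartile filter, the intensity trend, array weights and the ordinary t statistic. The direction of a list was compared only where it was called in the main fit or under the alternative. For 162 genes under the naming rule, 2393 of 2589 values under alternatives kept side and direction, 191 lost the threshold and 5 gained it. For the 38 lists, 487 of 530 values kept their side of the threshold, whatever the direction where uncalled in both, 29 lost it and 14 gained it. The count of probe sets that rose was 2156 with an offset of 32, against 1426. The ordinary t statistic called 1972 probe sets, 915 higher and 1057 lower. A minimum change of 1.5-fold left 1753 and an adjusted p under 0.01 left 1474; both are stricter thresholds. With each array left out in turn, which also removes a degree of freedom, 1807 to 2578 changed, 733 to 1105 higher and 1074 to 1473 lower, the fewest without scramble replicate 2. Camera with an estimated correlation called 0 lists, 0 higher and 0 lower, and fry called 11 higher against 7. Histones were lost with fry (adjusted p = 0.0820). The cause was not tested for the offset, the t statistic or fry. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom, a stricter reference than with the preset. For the shifted list simulated with independent noise, the camera adjusted p was 1.57e-24 with the preset and 0.0323 with the estimate. A correlation above the preset 0.01 was thus not needed for a list to lose its call. How much correlation added in the data was not tested. RNA interference and immediate early genes had estimated correlations of 0.0074 and −0.020, and both lost theirs (camera with an estimated correlation, adjusted p = 0.154). Zc3h10 stayed below scramble and past no threshold under every alternative, from −0.52 to −0.22 with an array left out. Scaling by quantile, median or cyclic loess gave 3329, 3160 and 3265 changed probe sets. The replicate numbers did not pair the arrays: deviations from the group means of same-numbered arrays correlated at 0.077, −0.017 and 0.028, and not every array correlated best with its own number. With the number as a block, 2455 probe sets changed, 1031 higher and 1424 lower, 23 lists were called, and Zc3h10 was at −0.34 (adjusted p = 0.212). The arrays give no detection calls, so signal over background limits dim genes most: 1375 olfactory and vomeronasal receptor genes, mostly silent outside sensory tissue, had a median log2 of 2.34 and an upper limit of their central 95% of 4.34 on the scramble arrays, where Ucp1 was at 4.00 and Ppargc1a at 4.11.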

Other observations

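The gene sets of the next paragraphs, and the tests of array labels by correlation, of other small RNAs, of the spread of adipocyte markers and of interferon genes, were chosen only after the results were seen.

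Some genes between Dlk1 and Dio3, an imprinted neighbourhood rich in noncoding RNAs, were higher in the Zc3h10 shRNA cells. Of 54 measured genes in this interval, 13 rose, 23 adjusted over the list alone, with a median of 0.42, or 0.11 with an offset of 32 before log2 (camera without the offset, p = 2.11e-11; p = 0.00566 with an estimated correlation, both unadjusted). Array medians were 3.51, 3.51 and 3.38 on scramble arrays 1 to 3 and 3.95, 4.02 and 4.01 on shRNA arrays 1 to 3, all under the 4.34 that bounds the central 95% of silent receptor genes, so the size of the rise is uncertain. Besides Rian, the risers included the small nucleolar RNAs AF357425 (1.07 ± 0.13, SE) and DQ267102 (1.08 ± 0.16), which lie with Rian, and Mir493 (1.95 ± 0.24), Mir453 (1.94 ± 0.22) and Mir382 (1.35 ± 0.16). The protein-coding ends did not pass, with Dlk1 at −0.07 ± 0.12 (adjusted p = 0.809) and Dio3 at 0.17 ± 0.12 (adjusted p = 0.498), nor did Meg3 at 0.53 ± 0.24 (adjusted p = 0.265). Outside the interval 10 of 435 microRNA genes rose and 1 fell, against 8 rises of 43 inside; adjusted over the list alone, 4 rose and 0 fell outside and 18 rose inside. Many microRNA probe sets were dim, Mir493 and Mir382 with scramble mean log2 values of 3.03 and 3.67, and such probe sets read precursors as well as any host transcript. Neighbours read through a shared host transcript are not independent, so the camera p at the preset correlation of 0.01 can be too small.

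Families of genes sharing a symbol stem held further groups: of 622 families of at least 5 genes, camera called 17 lower and 4 higher, and 0 with an estimated correlation (adjusted p = 0.995 for those named here). With 4 residual degrees of freedom and adjustment over 622 families, the estimated form had little room to call any family. Its 0 calls therefore do not count against them. Peroxisome assembly genes (Pex) fell in 7 of 14 cases, median −0.42 (camera, adjusted p = 2.34e-05), led by Pex11a at −1.67 ± 0.10. Coenzyme Q synthesis genes (Coq) fell in 6 of 11, median −0.50 (adjusted p = 7.27e-05), led by Coq8a at −1.58 ± 0.12, and aldehyde dehydrogenases (Aldh) in 10 of 21, median −0.47 (adjusted p = 0.000382), led by Aldh3b2 at −1.49 ± 0.12. Kinesins (Kif) rose in 9 of 38, median 0.24 (adjusted p = 0.000232), of which Kif11, Kif20a and Kif23 also stand in the cell cycle list. Intraflagellar transport genes (Ift), which build cilia, rose in 4 of 14, median 0.36 (adjusted p = 0.0107), led by Ift57 at 0.68 ± 0.09. All these medians kept their sign under quantile, median and cyclic loess scaling and with the offset of 32, which took Kif to 0.12 and Aldh to −0.28. The Kif count was 4 without scramble replicate 2 and 5 without shRNA replicate 3, and the Ift count was 1 without scramble replicate 2, scramble replicate 3 or shRNA replicate 3 and 2 without shRNA replicate 1 or 2. The largest fall on the array among named genes, outside the naming rule, was 2610528A11Rik at −3.74 ± 0.76 (adjusted p = 0.0192), with shRNA arrays at log2 8.79, 5.68 and 5.62 against 10.9, 10.0 and 10.4 for scramble, and it passed in 1 and missed in 5 of the 6 fits with an array left out (largest adjusted p = 0.0715, without shRNA replicate 3, where the change was −3.21).

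The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 3238 probe sets and was the 1 split to call as many, and the highest of the others called 0 by limma, with 845 to 1618 at an unadjusted p under 0.05 and 0 by the ordinary t statistic. Every other split put arrays of both groups on each side, so the difference between the groups widened the spread within each side. The low counts of those splits therefore do not give a rate of calls by chance.

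The Zc3h10 transcript was 1.27-fold lower without passing the threshold, beside 3238 changed probe sets. An array carrying the other group's label is argued against, since over all probe sets the smallest correlation within a group lay 0.00403 above the largest between groups. A single array with an atypical Zc3h10 value stays open. The condition written beforehand against it was met: every fit with an array left out kept its direction and none passed (limma, smallest adjusted p = 0.0810). But those fits have fewer arrays, and without scramble replicate 1 the fall grew to −0.52, a move larger than its SE of 0.17. The size of this move was not part of the condition written beforehand. A probe set held up by background stays open too: its scramble mean log2 of 5.04 lay 2.70 above the median of silent receptor genes, with 0.945% of them above it, but only 0.698 above the upper limit of their central 95%, less than a halving needs to stay clear. A modest loss of the transcript, which the hairpin could also have with a larger loss of protein, was not tested.

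Small nucleolar RNAs outside the Dlk1-Dio3 interval were lower as a class: 39 of 75 fell and 0 rose past the threshold (limma; 48 lower and 0 higher adjusted over the list alone; 69 of 75 below 0), with a median of −0.54 (camera, p = 1.06e-19; p = 0.0390 with an estimated correlation, both unadjusted) and examples such as Snord35b at −1.72 ± 0.20. Among the symbol families, Snord and Snora each had an adjusted p = 0.995 by camera with an estimated correlation, a form with little room to call any family. The 39 became 24 without scramble replicate 2 and 23 without shRNA replicate 3. Array medians of these RNAs were 6.70, 7.23 and 7.06 on scramble arrays 1 to 3 and 6.35, 6.11 and 6.39 on shRNA arrays 1 to 3. The groups did not overlap, but scramble array 1 lay nearer to shRNA arrays 1 and 3 than to scramble array 2. Lower host transcripts are argued against, since the median host change lay 0.669 above the median of 62 small nucleolar RNAs with a measured host. That host median counts each of the 49 host genes once per small nucleolar RNA. A level-dependent scaling left in the deposited values is argued against too, since the median outside the interval was −0.556 after cyclic loess. What the scaling before deposit did to these RNAs was not tested. A lower recovery of all small RNAs cannot be told apart from a change in the cells, because only 16 genes of other small RNA classes were measured, fewer than the condition for this test required. Their median of −0.0853 lay 0.45 above that of the small nucleolar RNAs. The difference in means had an SE of 0.13 over genes, which does not measure the spread between arrays. These genes also split by class, with medians of 0.01 for 6 snRNAs and 0.08 for 3 RNase P type RNAs against −0.41 for 5 scaRNAs and −0.67 for 2 Y RNAs. A change in processing or stability of these RNAs with the Zc3h10 hairpin may also contribute and was not tested.

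Mature adipocyte markers fell together, with a median of −1.07. A level-dependent scaling left in the deposited values is argued against by a median of −1.09 after cyclic loess. The effect of the scaling before deposit was not tested. A loss of adipocytes with the same expression per cell cannot be told apart from a change in the cells. Among 12 markers of middle signal the changes ranged from −0.61 for Pcx to −1.70 for Aqp7, with an SD 3.21 times their mean SE. Markers also expressed in other cells would fall less, but Adipoq (−0.84 ± 0.08) and Aqp7 (−1.70 ± 0.13) also lay apart. A loss of adipocytes alone would leave no such gap only if adipocytes alone expressed both genes and their probe sets responded alike. Neither condition was tested. The rises of 9 of 24 progenitor and 26 of 40 cell cycle genes go with fewer adipocytes. Those counts became 5 and 13 without scramble replicate 2, Pdgfra and Mcm6 fell, and the progenitor gene Dlk1 was at −0.07 ± 0.12. An unequal innate response to the viruses stays open too: 0 interferon genes passed (limma; 5 at an unadjusted p under 0.05, 0 by the ordinary t statistic), but 2 passed and the list was called without scramble replicate 3 (adjusted p = 0.0489), and 1 passed without shRNA replicate 1, while Ccl2 (2.40), Ptgs2 (1.55) and Csf1 (1.28) rose and fry called the inflammatory list (adjusted p = 0.0194). A slower or partly reversed differentiation with the Zc3h10 hairpin, or an off-target effect of the hairpin, may each contribute, and 1 hairpin at 1 time point, with the timing of the exposure not given in the sources used here, cannot separate them.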
